A study of Mus musculus with 2 samples.

How the data were processed

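The data are Illumina mouse bead array measurements of total RNA from sorted S100A4+ cells, with 1 array for normal lung and 1 array for metastatic lung. Per the labels, RNA was extracted with a Qiagen RNeasy Plus Micro kit and amplified and biotin-labelled as cRNA with a NuGEN WT-Ovation Pico kit, a procedure made for very small amounts of RNA. Whether RNA of several animals was pooled is not given in the sources used here. The design text names the sorting of GFP-positive cells from transgenic mice, and the tumour-bearing mice carried 4T1 tumours.

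The deposited non-normalized table holds an intensity per probe and array, on a linear scale, with no background subtracted and no normalization between arrays. Beside each intensity the authors deposited a detection p-value, so named per the file headers, which moves in even steps of 0.00125, as a rank among an array's negative control probes does. BeadStudio, the array maker's software, is named in the submitters' processing notes without a version. The scanner and the image settings are not given in the sources used here. A further table holds the authors' processed intensity values, with medians of 87.2 (normal) and 96.0 (metastatic). Set against the non-normalized intensities, each of its columns was a straight-line rescaling of the same array, with a slope of 1.08 and an added constant of 9.31 for normal lung, and a slope of 0.942 and an added constant of 33.8 for metastatic lung. The largest residuals of these lines were 0.00795 and 0.00641 intensity units. The scale of that table is therefore linear and not centred, while the method behind it stays unknown, and it was used only as an alternative.

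The non-normalized intensities were background-corrected by a normal-exponential model whose background was estimated from the detection p-values (neqc in limma 3.58.1, R 4.3.3), with an offset of 16, then quantile-normalized and taken to log2. The estimated background had a mean of 58.3 and an SD of 7.04 on the normal-lung array, and a mean of 54.5 and an SD of 7.56 on the metastatic-lung array. The 10 brightest probes held 3.02% and 3.08% of the signal above background. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9. All ratios are metastatic lung over normal lung, on the scale of values with the offset added, which understates the ratios of dim genes.

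Probes were named from a platform annotation of 2016, with symbols updated through gene identifiers to the RefSeq genes of GRCm38.p6. One symbol was found for 23978 probes, several for 0 and none for 1719, and these are unnamed here. Of the named probes, 23962 were matched by gene identifier and 9 by accession, 7 kept the platform symbol, and 8 symbols changed. The build behind the probe design is not given in the sources used here, so that no coordinates are printed. The probes named 16590 genes, 4776 of them through more than 1 probe. Each gene was represented by the probe with the highest mean of both normalized values, and was called detected where that probe had a detection p below 0.01.

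With 1 array per group there is no test. A gene was counted as higher where its log2 ratio was at least 1 and it was detected on the metastatic-lung array, and as lower where the ratio was -1 or less and it was detected on the normal-lung array. Where a gene was detected on 1 array only, its fold is reported as a bound, for which the dim value was raised to the lowest value among detected probes of that array (log2 5.25 for normal and 5.36 for metastatic lung). Counts of genes, list medians and percentiles take the measured ratios unless bounds are named. The genes named are the 12 with the largest ratio each way among genes detected on both arrays and above the median brightness of such genes on their brighter array. To these were added the 6 brightest genes detected on 1 array only for each array, the study genes S100a4, Vegfa and Tnc, up to 4 members with the largest ratio of each gene list, and the sex-linked genes. One gene that this rule names is not reported here. The 38 lists hold 890 entries, of which 802 were on the array. A list with at least 5 detected members was set against 10000 random lists of detected genes matched in 20 bins of mean value, and was called shifted above the 97.5th or below the 2.5th percentile. The lists, the thresholds, the rule for named genes and the alternatives were chosen before the data were examined.

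The spread between probes stands in for a technical error. Over 1648 genes with 2 probes detected on both arrays, the ratios of the probes differed with an SD of 0.25 on the log2 scale per probe. Of 159 such genes that were at least 2-fold different by the brightest probe, the second probe had the same sign for 156 and was itself at least 2-fold different for 109. This spread covers neither the sort, the animals nor the amplification. The procedure was tested on simulated arrays of this comparison with 16590 genes, 50 changed at each fold and noise of the same SD. It called 4 of 50 genes changed 1.5-fold, 18 of 50 changed 2-fold, 44 of 50 changed 3-fold and 48 of 50 changed 4-fold, 0 of them the wrong way, and 24 of 8069 unchanged detected genes. The changed genes were drawn from genes detected on both arrays, so genes detected on 1 array only are not covered. Of 200 simulated lists of randomly drawn unchanged genes 4.0% were called shifted, a share that the percentile limits set in advance. All 40 random lists with 1 added to their log2 ratios after normalization were called, a shift large enough to make this certain. Neither result tests lists whose genes vary together.

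The alternatives were no background correction, an offset of 50, median scaling or cyclic loess in place of quantile normalization, the authors' processed values, other detection rules, the mean of all detected probes of a gene, thresholds of 1.5-fold and 3-fold, and bright genes only. All intensity columns of both arrays were used.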

Results

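Gene expression was measured on Illumina bead arrays in mouse stromal cells that were sorted by fluorescence for S100A4, a calcium-binding protein found in fibroblasts and in many migrating and immune cells. The mice were BALB/c animals carrying an S100A4-GFP transgene, so that green fluorescence marked the cells. The cells came either from normal lung or from lung with metastases, in mice bearing tumours of 4T1, a mouse mammary carcinoma line that spreads to the lung. Each group had 1 array and there were no replicates, so no difference below has a replicate check, no p-value was computed, and the array and the condition cannot be told apart. The number of arrays limits the precision of every value. Each array carried 25697 probes, and the median signal was 72.2 on the normal-lung array and 66.1 on the metastatic-lung array. A detection p below 0.01 was reached by 10946 probes (42.6%) on the normal-lung array and by 10510 probes (40.9%) on the metastatic-lung array. In genes, each represented by its brightest probe, 6904 were detected on both arrays, 820 on the normal-lung array only and 404 on the metastatic-lung array only.

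The comparison asked how S100A4+ cells of a lung with metastases differ in gene expression from those of a normal lung. Neutrophil and granulocyte precursor markers were higher as a group in the metastatic-lung cells. Among their granule protein genes, myeloperoxidase (Mpo) was at least 51.3-fold higher, cathepsin G (Ctsg) at least 17.3-fold higher and lactoferrin (Ltf) 12.9-fold higher. Endothelial genes were lower as a group, with a median 7.15-fold difference over 16 detected markers, among them Robo4 (11.7-fold lower) and Ramp2 (11.5-fold lower). Fibroblast, lymphocyte, dendritic cell and macrophage markers and the collagen and matrix glycoprotein genes were also lower as groups. Cytokine, cell cycle and heat shock genes were higher as groups, and Vegfa, the main vascular endothelial growth factor gene, was 2.69-fold higher.

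In total 479 genes were at least 2-fold higher in the metastatic-lung cells and 826 were at least 2-fold lower. Of these, 350 higher and 485 lower genes were detected on both arrays. A gene detected on 1 array only has a ratio that is known only as a bound. It is given below as "at least N-fold", with the value on the bright array set against the higher of the dim array's lowest detected value and the gene's own value there. Such a bound holds for the processing used here and was smaller where a constant stays in the signals: for Ctsg it was 7.27-fold in the authors' processed values, against 17.3-fold. With such genes counted at their bounds, 414 were at least 2-fold higher and 663 at least 2-fold lower. At least 8-fold differences by the same count were found for 12 higher and 42 lower genes. Among the genes detected on both arrays, 87.9% differed by less than 2-fold, and the arrays' normalized values correlated across genes with a Pearson r of 0.908, where genes are not independent replicates.

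**Figure D1:**
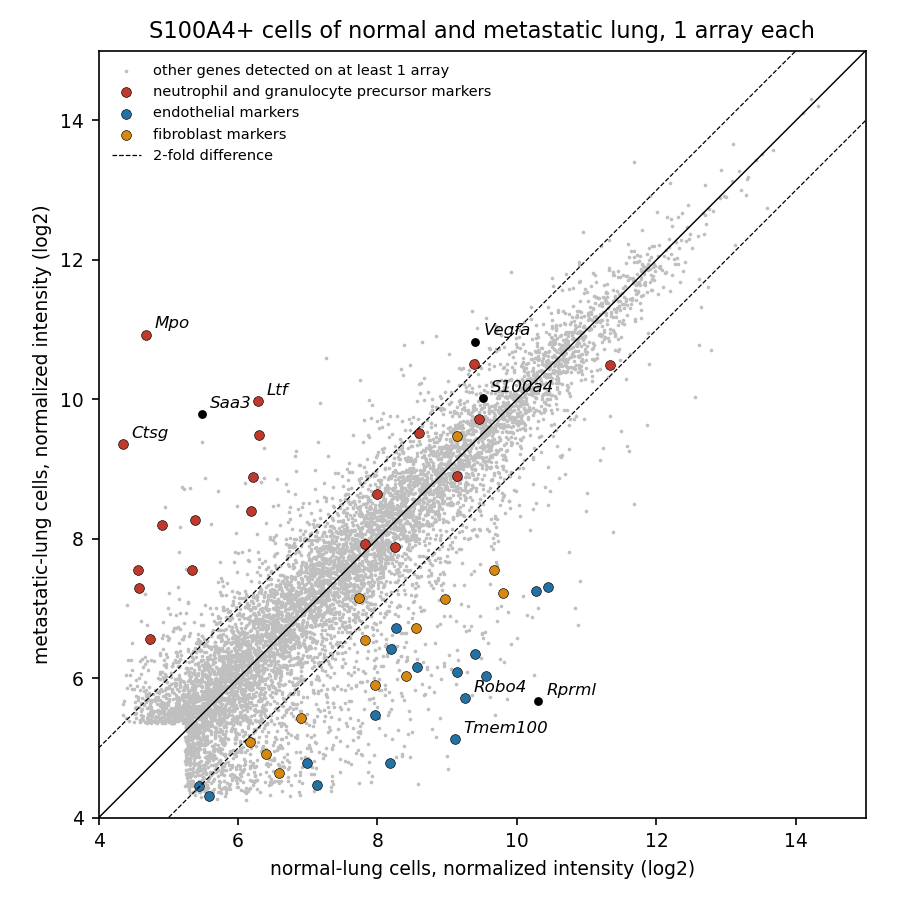
Normalized log2 intensity of each gene detected on at least 1 array, with the normal-lung cells on the x axis and the metastatic-lung cells on the y axis, 1 point per gene and 1 array per group. Red, blue and orange points are neutrophil and granulocyte precursor, endothelial and fibroblast markers, black points are other named genes, the solid line marks equal values and the dashed lines a 2-fold difference; the median log2 ratio was 2.22 for the red points, -2.84 for the blue points and -1.83 for the orange points.

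S100a4 itself, the gene whose reporter the cells were sorted on, was well above background on both arrays. Its single probe had a signal of 743 in the normal-lung cells and 1122 in the metastatic-lung cells, a normalized log2 ratio of 0.51 (1.43-fold higher). Vegfa was represented by 3 probes. The brightest had a signal of 691 in normal-lung and 1928 in metastatic-lung cells (log2 ratio 1.43, 2.69-fold higher). Another had a signal of 146 and 472 (log2 ratio 2.08, 4.23-fold higher), and the remaining Vegfa probe was detected on neither array. Tnc, which encodes the matrix glycoprotein tenascin-C, was represented by 6 probes, none of which was detected on either array. The lowest detection p of a Tnc probe was 0.0426 in the normal-lung cells and 0.168 in the metastatic-lung cells, so that no fold is given for Tnc. Of the sex-linked genes read as a check of the samples, Xist was detected on both arrays with a log2 ratio of -0.07 on its brightest probe and 0.42 on its other probe. The Y-linked Eif2s3y and Kdm5d were detected on neither array, and Uty had a detection p of 0.00627 and 0.00752, close to the threshold.

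**Figure D2:**
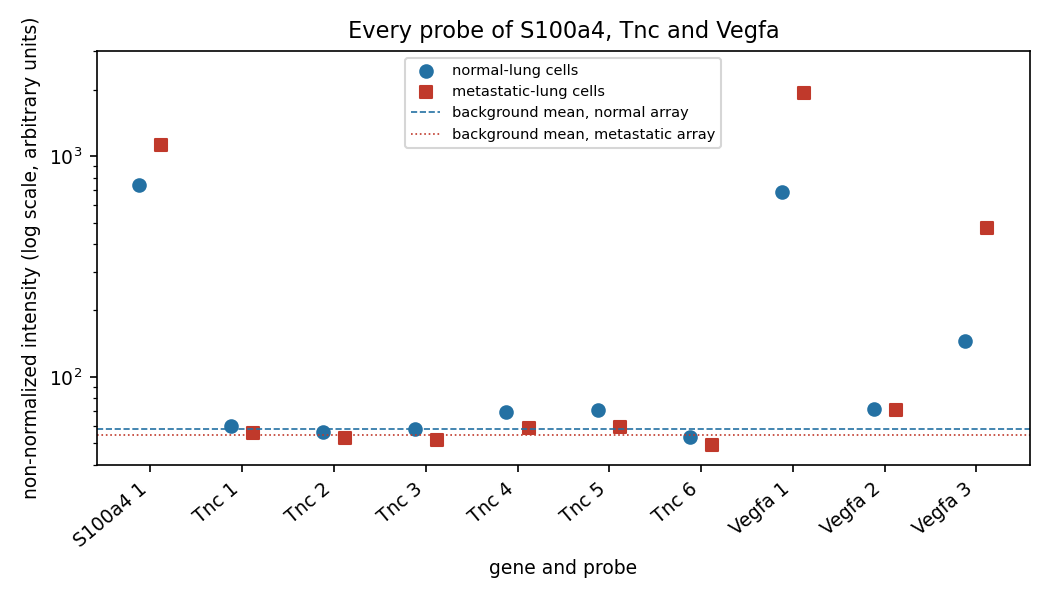
Non-normalized intensity, on a log axis in arbitrary units, of every probe of S100a4, Tnc and Vegfa on the normal-lung array (blue circles) and the metastatic-lung array (red squares), with the mean background of each array as a horizontal line at 58.3 (normal) and 54.5 (metastatic). The 6 Tnc probes lie near the background on both arrays, while the S100a4 probe and the brighter Vegfa probes lie far above it and are higher in the metastatic-lung cells.

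Among genes detected on both arrays and bright on at least 1 of them, the largest difference upward was that of Saa3, an acute-phase serum amyloid A gene, at 19.9-fold (log2 ratio 4.31). Mefv, which encodes the inflammasome protein pyrin, had a log2 ratio of 3.90, and Ltf followed at 3.69 (12.9-fold). Gpat3, an acyltransferase of triglyceride synthesis, was 10.7-fold higher, B3gnt5, a glycosyltransferase of glycolipid synthesis, 10.1-fold, and Hspa1a, an inducible heat shock protein, 10.1-fold. The antimicrobial cathelicidin gene Camp was 9.19-fold higher, the spermine oxidase gene Smox 7.67-fold and Clec4e, a C-type lectin receptor, 6.86-fold. The stefin genes Cstdc6 and Stfa1, which encode cysteine protease inhibitors, were 7.54-fold and 7.35-fold higher. Genes detected on the metastatic-lung array only included, besides Mpo and Ctsg, the eosinophil granule gene Prg2 (at least 11.3-fold higher), Rhov (at least 11.03-fold), the mucin gene Muc13 (at least 9.23-fold) and Stfa2 (at least 7.71-fold). Stefin genes are near-identical copies of each other, as are Hspa1a and its neighbour Hspa1b, so that the probes may share transcripts and the gene assignment is uncertain.

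The largest difference downward was that of Rprml, at 24.6-fold (log2 ratio -4.62). Hoxb5, a homeobox gene, and Flvcr2, a membrane transporter gene, were each 18.4-fold lower. Tmem204 was 17.8-fold lower, the endothelial receptor gene Gpr182 17.3-fold, the non-classical MHC gene H2-M2 14.7-fold and Ripply3, a transcriptional corepressor gene, 14.2-fold. Cav1, which encodes the caveolar coat protein caveolin-1, was 12.1-fold lower, and Hey1, a target gene of Notch signalling, 11.95-fold. Robo4, an endothelial guidance receptor gene, was 11.7-fold lower, Ramp2, a subunit gene of the adrenomedullin receptor, 11.5-fold, and Emp2 11.4-fold. Genes detected on the normal-lung array only included Tmem100 (at least 13.5-fold lower in the metastatic-lung cells) and both the vascular peptide gene Apln (at least 12.6-fold) and its receptor gene Aplnr (at least 12.5-fold). The endothelial proteoglycan gene Esm1 (at least 11.2-fold lower), Ncald (at least 10.8-fold) and the collagenolytic protease gene Ctsk (at least 9.31-fold) were also among them. Of the 36 genes with the largest differences, 9 had further probes. All 10 further probes that were detected had the same sign, and 4 were detected on neither array, among them 1 of Flvcr2 and the remaining probes of Robo4. Several detected further probes had a much smaller log2 ratio than the named probe: -0.67 for Gpr182 (named probe -4.11), 1.17 for Ltf (3.69), 1.84 for Gpat3 (3.42) and 1.10 for 1 of the Smox probes (2.94).

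Groups of genes were compared with 10000 random lists of the same size, matched on mean value, as a description of these arrays. Of 34 lists with enough detected members, 5 had a median ratio shifted upward against their random lists, 21 had one shifted downward and 8 lay within them. Of 34 lists of unrelated genes 1.7 would be called shifted. That number is no gauge of chance here, because the lists share members, genes of 1 cell type can move together, and each group had 1 array. Below, each median is followed in brackets by the median with 1-array genes at their bounds where the values differ, and counts of 2-fold differences take such genes at their bounds.

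Neutrophil and granulocyte precursor markers had the highest median of the cell type lists. The list had 20 detected members with a median log2 ratio of 2.22 (2.14), above all its random lists; 13 were at least 2-fold higher and 0 at least 2-fold lower. Over the 14 members detected on both arrays the median was 1.03, since granule genes such as Mpo and Ctsg were detected in the metastatic-lung cells only. S100a9, a calcium-binding protein gene abundant in neutrophils, had a log2 ratio of -0.85, with signals of 2522 and 1542, and S100a8 of 1.13, with signals of 685 and 1562. The mast cell and basophil list had 6 detected members and a median of 0.58 (0.46), at the 98.69th percentile, a call kept in only 4 of 9 alternative settings. The basophil protease gene Mcpt8 was 3.72-fold higher and the cytokine gene Il6 3.24-fold higher, the log2 ratio was -1.32 for Gata2 and 0.64 for Cpa3. Monocyte markers went both ways, with a median of 0.32 over 10 genes, at the 92.85th percentile. F13a1 was 4.32-fold higher, while Ace was 7.29-fold lower, the chemokine receptor gene Cx3cr1 4.44-fold lower and Treml4 at least 3.31-fold lower.

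Endothelial markers had the lowest median of all lists, -2.84 (-2.65) over 16 detected genes, below all random lists. Of these, 14 were at least 2-fold lower, 10 were detected on both arrays, and all 16 had a ratio below 0. Plvap, which encodes a protein of endothelial fenestrae, was at least 7.04-fold lower, beside Tmem100, Robo4 and Ramp2. Fibroblast markers had a median of -1.83 (-1.48) over 13 genes, also below all random lists, with 10 at least 2-fold lower and 0 higher. Inmt was 5.95-fold lower, the growth factor receptor gene Pdgfra 5.21-fold, Thy1 4.31-fold and the dermatopontin gene Dpt 4.15-fold. Only 4 smooth muscle, myofibroblast and pericyte markers were detected, too few for random lists. Desmin (Des) was 5.34-fold lower, and the log2 ratio was -0.86 for Tpm2, 0.09 for the smooth muscle actin gene Acta2 and -0.01 for Cspg4. Mesothelial markers had a median of -1.38 (-0.52) over 6 genes, at the 0.06th percentile, a call kept in 7 of 9 alternative settings, lost with no filter on detection and not testable with detection on both arrays, where the median was -0.02 over 3 genes. Gpm6a was 4.10-fold lower, Wt1 at least 1.69-fold, Krt19 at least 1.61-fold and Upk3b at least 1.28-fold.

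**Figure D3:**
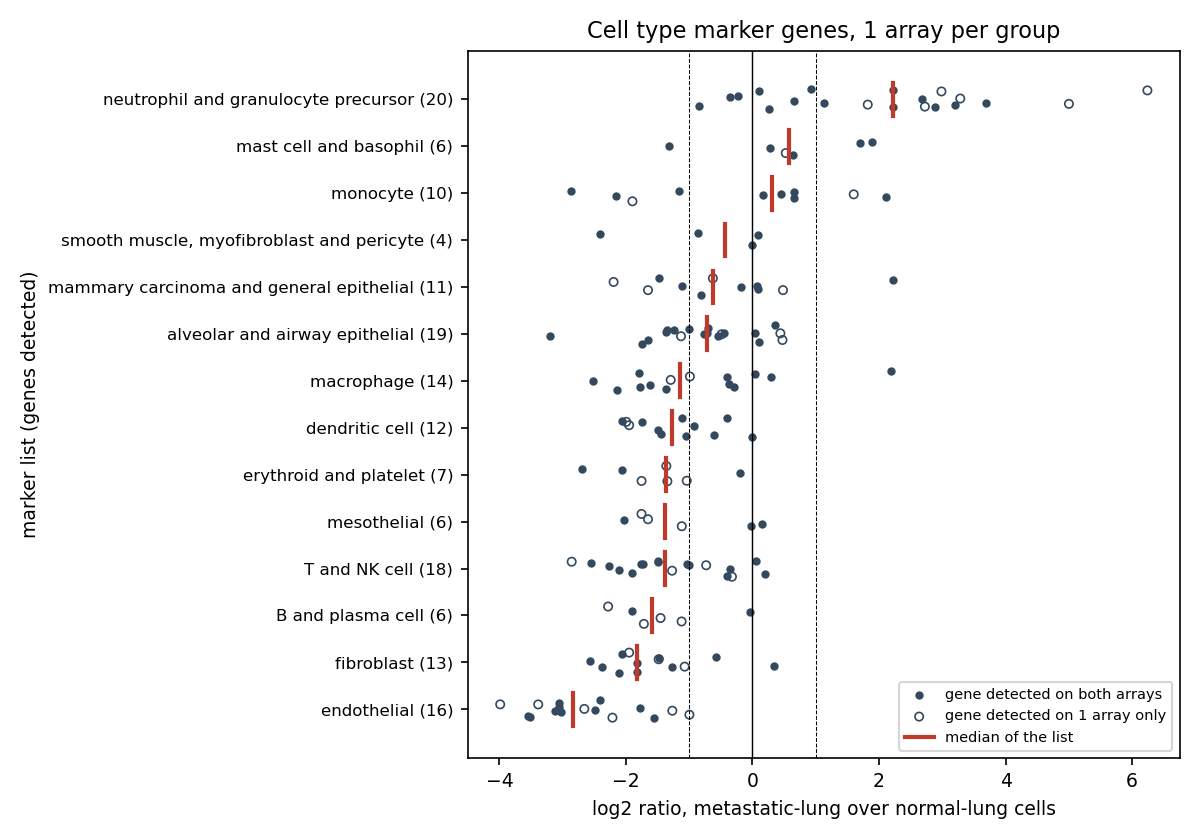
Log2 ratio of metastatic-lung over normal-lung cells (x axis) for each detected gene of 14 cell type marker lists (y axis, number of detected genes in brackets), 1 array per group. Filled points are genes detected on both arrays, open points are measured ratios of genes detected on 1 array only, whose size is known only as a bound, red bars are list medians and dashed lines mark a 2-fold difference; medians run from -2.84 for endothelial markers to 2.22 for neutrophil and granulocyte precursor markers.

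Lymphoid and antigen-presenting cell markers were lower. T and NK cell markers had a median of -1.39 (-1.26) over 18 genes, below all random lists, with 10 at least 2-fold lower. Cd8b1 was at least 5.32-fold lower, the granzyme gene Gzma 5.84-fold and the T cell receptor component gene Cd3d 4.82-fold. Thy1, counted above among fibroblast markers, belongs to this list too. B and plasma cell markers had a median of -1.58 (-0.85) over 6 genes, at the 0.02nd percentile, with 2 at least 2-fold lower. The median was -0.97 with detection on both arrays, over only 2 genes, and -0.52 with no filter on detection. The B cell receptor component gene Cd79b was 3.76-fold lower, Jchain at least 3.32-fold, Cd22 at least 1.84-fold and Blk at least 1.75-fold. Dendritic cell markers had a median of -1.28 over 12 genes, below all random lists, with 8 at least 2-fold lower. Itgax, the CD11c gene, was 4.16-fold lower, Fscn1 at least 3.85-fold, the chemokine gene Ccl17 3.37-fold and Cd209a at least 2.89-fold. MHC class II genes had a median of -1.02 (-0.93) over 10 genes, at the 0.01st percentile, all 10 with a ratio below 0. H2-DMb2 was 3.12-fold lower, H2-DMb1 2.70-fold, the invariant chain gene Cd74 2.38-fold and Ciita at least 1.36-fold. MHC class I and antigen processing genes had a median of -0.44 over 15 genes, at the 0.175th percentile, with none as much as 2-fold different. The log2 ratio was -0.70 for Tap2, -0.63 for Psmb9, -0.58 for H2-Q7 and -0.56 for Psmb10.

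Macrophage markers had a median of -1.14 (-0.70) over 14 genes, below all random lists, with 6 at least 2-fold lower and 1 higher. Chil3 was 5.72-fold lower, the lipid carrier gene Fabp4 4.39-fold and the mannose receptor gene Mrc1 3.46-fold. The endotoxin co-receptor gene Cd14 was 4.56-fold higher. Other members, named here after their values were seen, differed less. The log2 ratio was -0.30 for Adgre1, -0.37 for Cd163, -0.39 for Trem2, 0.04 for Lyz2 and 0.29 for Fcgr1. The list of alternatively activated macrophage and suppressive myeloid genes, of whose 19 detected members 10 belong to other lists as well, had a median of -0.37, at the 0.225th percentile, a call kept in 8 of 9 alternative settings, with 6 at least 2-fold lower and 2 higher. Besides Chil3, Retnla was 6.54-fold lower and Gpnmb 3.83-fold lower, while Il10, an anti-inflammatory cytokine gene, was 3.48-fold higher. Complement genes had a median of -0.77 (-0.47) over 8 genes, at the 0.74th percentile, a call kept in 7 of 9 alternative settings and lost with detection on both arrays (median -0.26) and with the authors' processed values. C1qb was 3.44-fold lower, Serping1 2.99-fold, C1ra 2.51-fold and C1qc at least 1.60-fold. Lysosomal genes had a median of -0.13 over 22 genes, at the 8.51st percentile. Atp6v0d2 was at least 3.94-fold lower, Lipa 2.31-fold and Cd63 2.14-fold, and the log2 ratio of Ctsd was -0.96.

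Alveolar and airway epithelial markers had a median of -0.73 over 19 genes, below all random lists, with 6 at least 2-fold lower. The secretoglobin gene Scgb3a1 was 9.15-fold lower, Cyp2f2 3.36-fold, the phosphate transporter gene Slc34a2 3.15-fold and the surfactant protein gene Sftpa1 2.56-fold. The mammary carcinoma and general epithelial list had a median of -0.63 (-0.56) over 11 genes, at the 1.16th percentile, a call kept in 5 of 9 alternative settings. In it, Perp was at least 2.95-fold lower, Wfdc2 2.77-fold lower and Krt19 at least 1.61-fold lower, while Lcn2, also a neutrophil granule gene, was 4.67-fold higher. Erythroid and platelet markers had a median of -1.36 (-0.76) over 7 genes, at the 0.04th percentile. The median was -2.06 with detection on both arrays, over only 3 genes, and -0.19 with no filter on detection. The platelet chemokine genes Ppbp and Pf4 were 6.47-fold and 4.17-fold lower, the platelet glycoprotein gene Gp5 at least 1.996-fold, and the hemoglobin gene Hba-a1, which has a near-identical copy, at least 1.69-fold.

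Collagen and matrix glycoprotein genes were lower as groups. Of 20 collagen genes on the array 5 were detected, with a median of -1.48 (-1.30), at percentile 0.20. The median was -0.78 in the authors' processed values and -0.24 with no filter on detection. The basement membrane collagen gene Col4a1 was 3.67-fold lower, Col4a2 at least 2.45-fold, Col1a2 at least 2.06-fold and Col3a1 2.79-fold. Matrix glycoproteins, proteoglycans and crosslinkers had a median of -0.88 (-0.49) over 26 genes, below all random lists, with 8 at least 2-fold lower and 2 higher. The median was -0.33 with detection on both arrays, at the 1.72nd percentile, and -0.22 with no filter on detection. Igfbp7 was 5.996-fold lower, Sparc 4.94-fold and Ogn at least 4.12-fold, whereas the thrombospondin gene Thbs1 was at least 7.60-fold higher. Matrix proteases and inhibitors went both ways, with a median of -0.27 (-0.24) over 18 genes, at the 2.48th percentile, a call kept in only 2 of 9 alternative settings. Macrophage elastase (Mmp12) was 4.69-fold lower and Timp2 3.91-fold lower, beside Ctsk, while neutrophil collagenase (Mmp8) was 4.64-fold higher. The TGF-beta and activin list had a median of -0.57 (-0.43) over 16 genes, at the 0.04th percentile, but 0.11 over the members detected on both arrays, where the direction turned, and the call was kept in 6 of 9 alternative settings. Tgfbr3 was at least 6.36-fold lower, Ltbp4 3.24-fold, the connective tissue growth factor gene Ccn2 3.14-fold and Tgfb2 at least 2.85-fold.

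Angiogenic factors as a list were lower, unlike Vegfa. The median was -1.38 (-1.09) over 17 genes, below all random lists, with 9 at least 2-fold lower and 2 higher. It was -0.62 with detection on both arrays, at the 0.53rd percentile, and -0.46 with no filter on detection. Sema3c was 8.003-fold lower, the stromal chemokine gene Cxcl12 7.60-fold, Igf1 7.53-fold and the endothelin gene Edn1 at least 3.21-fold. The 2 higher members were Vegfa and, named here after its value was seen, Hbegf, with a log2 ratio of 1.54. Chemokines had a median of -0.54 (-0.53) over 23 genes, below all random lists, with 7 at least 2-fold lower and 2 higher. Cxcl12, Ppbp and Pf4 were among the lower ones, and the neutrophil-attracting chemokine gene Cxcl3 was 4.75-fold higher. Cytokines and inflammatory mediators had a median of 0.79 over 26 genes, above all random lists, with 10 at least 2-fold higher and 1 lower. Saa3 and Lcn2 were among the higher genes, Csf2, the GM-CSF gene, was at least 2.39-fold higher, and Retnla was the lower gene. Interferon-induced genes had a median of 0.05 over 27 genes, at the 60.955th percentile. Oas2 was 3.80-fold higher, Oas1a at least 2.03-fold and Cxcl10 at least 1.54-fold, while Igtp was 2.29-fold lower. The S100 family had a median of 0.04 over 11 genes, at the 59.48th percentile. S100a8 was 2.18-fold higher, and the log2 ratio was -0.85 for S100a9 and -0.75 for S100g, while S100pbp, which encodes a binding partner of an S100 protein, was at least 1.36-fold higher.

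Cell cycle genes were higher, with a median of 0.84 (0.69) over 32 genes, above all random lists; 9 were at least 2-fold higher, 0 lower, and 30 had a ratio above 0. The centromere histone gene Cenpa was 4.00-fold higher, the survivin gene Birc5 2.94-fold, the DNA topoisomerase gene Top2a at least 2.69-fold and the replication licensing gene Cdc6 2.48-fold. Heat shock and chaperone genes had a median of 0.54 over 20 genes, above all random lists, with 3 at least 2-fold higher and 0 lower. These were Hspa1a, Hsph1 (4.26-fold) and the endoplasmic reticulum chaperone gene Hspa5 (2.001-fold), and Pdia4 had a log2 ratio of 0.99. Immediate-early and dissociation-induced genes had a median of -0.32 over 26 genes, at the 0.06th percentile, a call lost with no filter on detection, with 5 at least 2-fold lower and 3 higher. Klf2 was 3.08-fold lower and Egr1 2.49-fold lower, while Ier3 was 3.33-fold and Nr4a2 2.99-fold higher. Hypoxia and glycolysis genes had a median of 0.24 over 20 genes, at the 95.94th percentile, with 5 at least 2-fold higher and 1 lower. The hypoxia-inducible factor gene Hif1a was 2.98-fold higher, Ndrg1 2.41-fold and the glucose transporter gene Slc2a1 2.37-fold, beside Vegfa.

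Housekeeping groups differed little. Oxidative phosphorylation genes had a median of 0.03 over 41 genes, at the 62.01st percentile, with 0 at least 2-fold different. The log2 ratio was 0.65 for Cycs, 0.42 for Ndufs3 and 0.38 for Atp5g1, and Atp5o was at least 1.18-fold higher. Ribosomal protein genes had a median of -0.07 over 43 genes, at the 13.75th percentile. Rpl5 was 2.21-fold lower, and the log2 ratio was 0.90 for Rpl4, 0.69 for Rpl6 and 0.66 for Rpl27a. Cholesterol and fatty acid synthesis genes had a median of -0.12 (-0.01) over 18 genes, at the 22.13th percentile. Lss was 2.48-fold and Sqle 2.02-fold lower, and the log2 ratio was 0.68 for Acsl3 and -0.62 for Scd1.

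Settings that leave a constant in the signals gave smaller ratios and fewer genes. In the authors' processed values 159 genes were at least 2-fold higher and 422 lower, and the median was 1.39 for the neutrophil and granulocyte precursor list and -1.84 for the endothelial list.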

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

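All the alternatives here were planned, and none was chosen after the results were seen. Against 479 genes higher and 826 lower, no background correction gave 186 and 422, an offset of 50 gave 239 and 513, and the authors' processed values gave 159 and 422. By construction each of these keeps or adds a constant in the signals, which pulls ratios of dim genes towards 1; all of these genes were among the 479 and 826, except 3 of the 422 lower genes of the authors' values. Detection on both arrays left 485 lower genes and 350 higher, because fewer genes qualify. Bright genes only gave 227 and 346 for the same reason. Thresholds of 1.5-fold and 3-fold gave 1300 and 120 higher genes, and 1513 and 391 lower genes. Median scaling (442 and 898), cyclic loess (382 and 926) and the mean of detected probes (464 and 802) stayed within 1.5 times, and a detection p below 0.05 or no filter on detection changed neither count. The lower genes made up 63.3% of all genes counted, and 58.1% to 72.6% under the alternatives that kept the 2-fold threshold. The authors' processed values moved the median of all genes to 0.18 on the log2 scale. The number of shifted lists, 26, was 19 to 25 under the 9 alternatives. The log2 ratio of S100a4 ran from 0.43 to 0.61. That of Vegfa ran from 1.29 to 1.52, except for 1.75 with the mean of detected probes, which takes in its second probe. Tnc, undetected, moved from -0.22 to 0.064 in the authors' processed values. The TGF-beta list, with a median of -0.57, turned to 0.11 with detection on both arrays and to 0.0042 with no filter on detection; the cause was not tested. Of 1389 values for 159 other named genes, 1041 stayed within the probe spread and 348 moved beyond it, and no gene counted as higher or lower changed sign. The 1041 include the values under other detection rules, which cannot alter a gene's ratio. Most values moved beyond the spread where a constant stays in the signals: 117 of 159 with no background correction, 116 with the authors' processed values and 101 with an offset of 50. Of 306 list medians 205 stayed and 99 moved, and the remaining 2 are those of the TGF-beta list, the only sign changes among shifted lists. Detection on both arrays gave no value for Tnc and left the B and plasma cell, mesothelial, erythroid and platelet, and collagen lists with too few genes for random lists. Signal over background sets the limit for the 820 and 404 genes detected on 1 array only, whose ratios are bounds. The bound for Mpo was at least 51.3-fold, and 20.1-fold to 50.2-fold under other background and normalization settings; that for Ctsg was 17.3-fold, and 7.27-fold to 17.1-fold. No paired analysis was possible because each group had 1 array, and for the same reason no replicate could be left out.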

Other observations

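All tests in this part were chosen after the result was seen, except the comparison of further precursor and further mature neutrophil genes. The 6 gene lists of the next paragraphs were also written after the genes with the largest differences had been seen, so that their percentiles describe these arrays and are not independent evidence.

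Genes of the NRF2 antioxidant response, none of which was among the genes with the largest differences, were higher as a list in the metastatic-lung cells. The list had 14 detected members with a median log2 ratio of 0.61, above all 10000 matched random lists, with 4 at least 2-fold higher and 0 lower. The cystine transporter gene Slc7a11 was 4.08-fold higher, the sulfiredoxin gene Srxn1 3.96-fold, the heme oxygenase gene Hmox1 3.26-fold and Sqstm1 2.01-fold, while Prdx1, Fth1, Tkt and Me1 had log2 ratios of -0.03, 0.10, -0.13 and -0.83. Pattern recognition C-type lectin and inflammasome genes had a median of 0.73 over 15 genes, also above all random lists, with 5 at least 2-fold higher. Of the 15, 2 were among the genes with the largest differences. Beside Mefv and Clec4e the higher genes were Clec4d (4.22-fold), Nlrp3 (3.45-fold) and Casp4 (2.02-fold). Casp1, Pycard, Clec7a, Clec4n and Il18 had log2 ratios of -0.02, -0.17, -0.20, -0.36 and -0.89. In polyamine and arginine metabolism Smox was 7.67-fold and the arginase gene Arg2 5.74-fold higher, and the cationic amino acid transporter gene Slc7a2 at least 7.50-fold lower. The list's median was 0.27 over 10 genes, at the 91.5th percentile.

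Eosinophil genes parted. Prg2, the major basic protein gene, was at least 11.3-fold higher, whereas the eosinophil ribonuclease genes Rnase2a and Ear10, members of a family of close copies, had log2 ratios of -3.24 and -2.59, and Siglecf of -1.62. Siglecf also belongs to the macrophage list, which was lower, so these falls need not come from eosinophils. The median was -1.62 over 5 genes, at the 0.08th percentile. Notch and apelin pathway genes had a median of -2.68 over 8 genes, below all random lists. Of these, 3 were among the genes with the largest differences, seen before the list was written, so the fall rests in part on them. Notch4, a receptor of endothelial cells, was 9.17-fold lower and the Notch target Nrarp 4.47-fold lower, beside Hey1, Apln and Aplnr. Notch1, Notch2 and Jag1 had log2 ratios of 0.08, 0.27 and 0.01. A list of caveola and membrane coat genes had a median of -2.59 over 6 genes, 2 of them among the genes with the largest differences. Cavin2 was 7.65-fold and Pmp22 4.74-fold lower, beside Cav1 and Emp2, while Emp1, a relative of Emp2, was 2.12-fold higher. Of the 1719 unnamed probes 735 were detected on at least 1 array, 49 were at least 2-fold higher and 57 at least 2-fold lower.

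The granule genes Mpo, Elane, Prtn3, Ctsg, Ltf, Camp, Ngp, Lcn2 and Mmp8 had a median log2 ratio of 2.72. More mature neutrophils in the metastatic sort would raise genes of mature cells alike. But 9 further mature genes, picked before their values were seen, had a median of -0.28 and an upper quartile of 0.89, below the granule genes' lower quartile of 2.22. Trem1 (1.54) and Mxd1 (1.34) were higher, and the 11 members of the fixed list that are not granule genes, with Stfa1, Stfa2 and Stfa3 as high as granule genes, had a median of 0.65. The 7 mature neutrophil genes of the fixed list, grouped after their values were seen, had a median of 0.26, with 1 at least 2-fold higher. The further mature genes thus did not rise as a set. This argues against more mature neutrophils as the whole cause for the granule genes, but does not exclude it. The granule genes were grouped after their values were seen. Other cells may share the mature genes, and macrophage and dendritic cell markers were lower. The lowest granule median over the background and normalization settings was 1.94. For genes grouped after their values were seen, this shows only that their height did not hinge on 1 such setting. A candidate explanation is more immature granulocyte precursors among the sorted cells. Of 12 further precursor genes on the array 7 were detected, among them Ms4a3 (at least 3.51-fold higher) and Cd177 (2.48-fold), with a median of 0.91. The rest were detected on neither array. This median takes the measured ratios of Ms4a3 and Olfm4, both detected on the metastatic-lung array only. The precursor median stayed below the 1 set beforehand, and Pglyrp1 had a ratio of -0.74. More precursors stay open as an explanation, as does a change within the S100A4+ cells themselves, which was not tested.

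Endothelial, fibroblast and lymphoid markers were lower in the metastatic-lung cells. Dilution of every other cell type by a single added type would lower all of them alike. The upper quartile of the endothelial ratios lay below the lower quartile of 124 markers of the other cell type lists, the neutrophil list left out, with a difference of -0.35 (-0.11 with bounds). This comparison alone does not decide on dilution as the whole cause for endothelial markers. Many of the 124 were too dim in normal lung to show so large a fall: Krt19 went from a normalized log2 value of 6.04 to 4.39, where it was undetected. The 124 also hold genes that were higher, such as Cd14 and F13a1 (log2 ratios 2.19 and 2.11). Of bright epithelial markers, Sftpc, Sftpd, Scgb1a1 and Abca3 fell less (-1.24, -1.35, -0.70 and -0.73) and Rtkn2 did not fall (0.03). Only Scgb3a1 fell as far (-3.19). The epithelial lower quartile was -1.29, with or without bounds, above the endothelial upper quartile of -2.10 (-1.74 with bounds). Of the 19 epithelial markers 15 were detected on both arrays. These values argue against an equal dilution of both cell types as the whole cause for the endothelial markers. For fibroblast, T and NK, B and dendritic cell markers dilution is neither excluded nor supported: their quartile ranges and the alveolar and airway epithelial range overlapped in all 10 pairs, by at least 0.0277, but the list medians spanned 1.10, more than the 0.5 that dilution was taken to allow. Before normalization between arrays, medians of probes detected on both arrays lay -0.01 (normal) and 0.01 (metastatic) log2 from their mean. For these probes, this argues against an even weakening of the metastatic-lung array, though it detected fewer probes (40.9% against 42.6%). Weaker RNA or amplification that struck some genes more than others stays open. The endothelial median of -2.83 relative to matched random lists does not decide on it, since those lists hold other genes. A biological loss of endothelial cells from the sort, lower endothelial gene expression and a different sorting gate were not tested and, with 1 array per group, may each contribute.

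In the authors' processed values all 6 Tnc probes read higher in the metastatic-lung cells, with log2 ratios of 0.06 to 0.26. This higher reading comes from the rescaling, since all 6 had a lower non-normalized signal on the metastatic-lung array, for example 59.3 against 70.8. The mean background was lower there too (54.5 against 58.3). The 14002 probes detected on neither array had a median of 0.22 in the authors' values. Of these probes 95% lay between -0.02 and 0.41, a range that holds all 6 Tnc probes. More Tnc transcript in the metastatic sort stays open, since no Tnc probe was detected on either array and the lowest detection p on the metastatic-lung array was 0.168. These arrays decide neither for nor against a difference in Tnc.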
